A study of Mus musculus with 6 samples.

How the data were processed

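The series holds RNA sequencing libraries of tumour tissue from C57BL/6 mice bearing Lewis lung carcinoma, 3 from mice given PBS and 3 from mice given isoleucine at 300 mg/kg, all sampled at day 18. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit. The labels also carry a cell type of mesenchymal stem cells, which does not match their description of the source as tumour, and the libraries were treated as tumour tissue. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2 and StringTie 1.3.1 were used; the notes give neither their roles nor their order. The genome build, the annotation, the counting step and whether counting used strand are not given in the sources used here, so no genomic coordinates are reported.

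The deposited table holds estimated counts per Ensembl gene, with 1 column per library, not scaled between libraries. The unit was read from the values: between 7.58% and 8.54% of the values of a library are not whole (tolerance 0.001), and library totals differ. The test design had been written for whole-number counts, and estimated counts were therefore rounded to whole numbers before testing. The table lists 22287 genes, 5284 of them with no count in any library, and 22253 gene IDs matched a symbol while 34 did not. Long noncoding genes such as Xist were not analysed here. Each column was assigned through the sample description that carries its name. Replicate numbers only name libraries within a group. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

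Library totals ran from 13216697 to 27258142 estimated counts, and the 10 most abundant genes took 6.52% to 7.04% of each library. Mitochondrially encoded genes took 1.44% to 1.51% of PBS libraries and 1.53% to 1.93% of isoleucine libraries, before scaling. Each pair of libraries was compared by chi-square over genes with a summed count of at least 20. The statistic per degree of freedom was 8.53 to 22.2, so no 2 libraries agreed within sampling noise and all 6 were used.

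Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with few counts were removed by filterByExpr with its minimum count of 10, leaving 13085 genes, and 9202 were left out. Libraries were scaled by TMM, with factors between 0.984 and 1.014. A robust quasi-likelihood model with treatment as its only term was fitted to all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 10.9%. Log2 fold changes are isoleucine relative to PBS, with their SE and 95% intervals. CPM values use TMM-scaled library sizes.

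Before the data were examined, 40 gene lists were fixed, covering the PTEN pathway, proliferation, amino acid and lipid metabolism, and markers of cell types that a mouse tumour can hold. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01, and adjusted over the 40 lists. Camera compares the genes of a list with other genes, and the preset correlation is low for lists whose members vary together between tumours, so each call is given with the p from an estimated correlation. A list's score in a library is the mean log2 CPM of its members, minus its mean over the 6 libraries.

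The genes named in the text followed a rule fixed at the same time. Pten, Mki67, Trp53 and Cdkn1a were always named. Up to 10 genes per direction were to be named among those past the threshold; with fewer than 5 past it, the 5 with the smallest p per direction were named among genes averaging at least 1 CPM whose groups did not overlap, leaving out unnamed gene models. Up to 3 members were named for each of the 8 lists with the smallest camera p, and Y-linked genes were checked. The rule named 39 genes. In a GENCODE mouse annotation (release M21), used only for which genes overlap, 2 of them overlap another gene of the table on the same strand (mt-Nd4l with mt-Nd4, and Xirp1 with Cx3cr1). For 11, an exon is overlapped by an exon of a gene on the opposite strand (Aldoa, Alas2, Cd22, Cdkn1a, Cyp51, Idi1, mt-Nd5, Myh2, Psd3, Selenop and Xirp2), and their counts are uncertain to that extent.

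The procedure was tested on simulated counts of 13085 genes with the real means and library sizes, for isoleucine against PBS. The 200 changed genes were drawn from those averaging at least 1 CPM, and genes were simulated independently with edgeR's fitted dispersions. Of these, edgeR recovered 60% of the 1.5-fold changes, 80% of the 2-fold changes and 96% of the 4-fold changes. It also called 14 unchanged genes, or 8.38% of the calls. In the real data Myh2 (0.161-fold) and Acta1 (0.199-fold) were not called. The recovery therefore does not carry over to genes that vary widely between libraries, and 0 calls do not exclude large differences. With no gene changed it called 2. Camera called 5 of 5 shifted lists and 0 of 35 unshifted lists, in simulated data without correlation between genes. The alternatives fixed with that rule were other scalings, no filter or a stricter filter (1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom with and without sample weights, a non-robust fit, other thresholds, an estimated correlation, fry, voom input for camera, and leaving out each library. Fits with the muscle or adipocyte list score as a covariate were added after the data were seen. Exact permutation tests of list scores were two-sided.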

Results

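Transcripts were measured by RNA sequencing in tumour tissue of C57BL/6 mice carrying Lewis lung carcinoma (LLC), a transplantable mouse lung cancer line. Mice of the treated group received isoleucine, an essential branched-chain amino acid, at 300 mg/kg into the peritoneal cavity each day, beginning on day 3. Mice of the control group received phosphate-buffered saline (PBS). The labels place all 6 libraries at day 18, with 3 libraries in each group. Total estimated counts were 19350571, 13216697 and 27258142 in PBS libraries 1 to 3 and 22149551, 17415750 and 21289941 in isoleucine libraries 1 to 3. Of 22287 genes, 13085 had enough counts to be tested. No pair of libraries agreed within sampling noise, and the pairwise correlations of log2 CPM (counts scaled to a common library total) across genes ran from 0.9763 to 0.9918. The Y-linked gene Ddx3y was counted in each of the 6 libraries, at 15.3 ± 1.28 CPM with isoleucine and 12.6 ± 0.913 with PBS (mean ± SD, n = 3).

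The comparison asked how transcript levels in tumours differed between isoleucine and PBS, in a study whose title concerns nuclear PTEN protein and the growth of lung cancer. Sterol and fatty acid synthesis genes and mitochondrially encoded genes were higher as groups in the isoleucine tumours, and endothelial, skeletal muscle, erythroid and B cell marker genes were lower as groups, by camera with a preset correlation. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.606. Pten mRNA and mitotic genes differed by less than the spread between libraries. At the level of single genes no difference passed: edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05, and its smallest adjusted p was 0.158. At an unadjusted p under 0.05 it gave 339 genes higher and 345 lower, 684 in all, where 654 were expected from uniform p-values. The 3 isoleucine values lay wholly above or below the 3 PBS values for 1435 tested genes, or 11%, where chance gives 10%. DESeq2, run as an alternative, called 17 genes higher and 32 lower, and limma-voom called 0 in either direction. Without PBS library 3, edgeR called 13 genes higher and 90 lower, and without PBS library 2 it called 1 higher.

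Pten, which encodes the lipid phosphatase that opposes PI3K signalling, stood at 84.2 ± 4.29 CPM in the isoleucine tumours and 82.1 ± 2.28 CPM in the PBS tumours (SD, n = 3). Its log2 fold change was 0.04 ± 0.06 (SE), with a 95% interval of -0.09 to 0.17 and an edgeR adjusted p of 0.995. The 31 genes of the PI3K, AKT and PTEN pathway list had a median log2 fold change of 0.01, with 16 members above 0 and 15 below. The 28 genes for ubiquitination and nuclear import of PTEN had a median of -0.002, and the 20 targets of FOXO transcription factors had a median of -0.06. Camera, a competitive gene set test, called none of these 3 lists. The scores of the list for ubiquitination and nuclear import of PTEN nevertheless did not overlap between groups. All isoleucine scores lay below all PBS scores, with a difference between group means of -0.0334. An exact two-sided permutation test of these scores gave p = 0.1, the lowest that 3 against 3 can give. Trp53, the gene of the p53 tumour suppressor, stood at 155.8 ± 3.49 CPM with isoleucine and 159.6 ± 4.37 with PBS. Cdkn1a, a cyclin-dependent kinase inhibitor, stood at 50.97 ± 0.064 and 55.5 ± 16.8 CPM, and the 25 p53 target genes had a median log2 fold change of -0.03.

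Proliferation was represented by lists for S phase and for mitosis. Mki67, which encodes the proliferation marker Ki-67, stood at 229.2 ± 20.01 CPM in the isoleucine tumours and 216.8 ± 6.76 CPM in the PBS tumours, a log2 fold change of 0.08 ± 0.07 (SE) with an edgeR adjusted p of 0.978. The 43 genes of G2 and mitosis had a median log2 fold change of 0.01, with 22 members above 0 and 21 below, and camera did not call them. The 42 genes of DNA replication and S phase had a median of 0.04, with 36 members above 0, and camera called them higher at an adjusted p of 0.00636. The adjusted p was 0.999 with an estimated correlation, and the preset-correlation call was also lost without PBS library 3, isoleucine library 1 or isoleucine library 2, at medians of 0.0283, 0.0348 and 0.041. The S phase median was 0.0603 without PBS library 1 and 0.0711 without isoleucine library 3, both called, and with the muscle score as a covariate the call was lost at an adjusted p of 0.323. The 14 cyclins of G1 and cyclin-dependent kinase inhibitors had a median of -0.06, which ran from -0.068 to -0.00337 when 1 library was left out. The 22 replication-dependent histones had a median of 0.11, and neither list was called. The histones were called higher without PBS library 3 (median 0.252) or isoleucine library 2 (0.207), and their median was -0.00826, -0.00783 and -0.00987 without PBS library 1, isoleucine library 1 and isoleucine library 3.

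**Figure D1:**
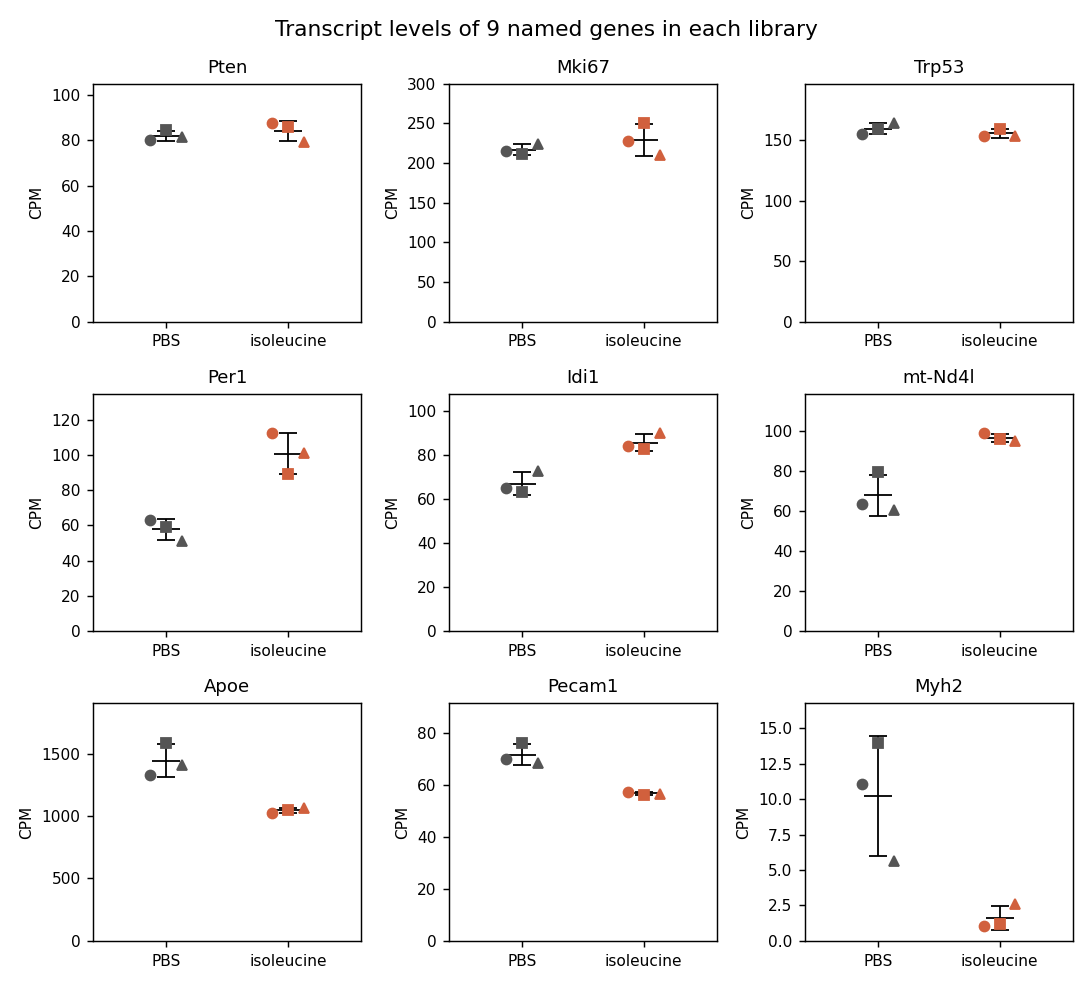
CPM (vertical axes, starting at 0) of 9 genes in the 3 PBS libraries (grey) and 3 isoleucine libraries (orange), with replicates 1, 2 and 3 as circles, squares and triangles and the group mean ± SD in black. Groups overlap for Pten, Mki67 and Trp53 and do not overlap for Per1, Idi1, mt-Nd4l, Apoe, Pecam1 and Myh2, none of which passed edgeR's adjusted p of 0.05. Per1, Idi1, mt-Nd4l, Apoe and Pecam1 were named by a rule that required groups not to overlap, so their separation was fixed by selection. Of all tested genes 11% did not overlap, where chance gives 10%.

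Genes of sterol and fatty acid synthesis were higher with isoleucine. Of 35 measured members, 33 had a log2 fold change above 0, the median was 0.22 (1.16-fold), and all 3 isoleucine libraries scored above all 3 PBS libraries. An exact two-sided permutation test of the scores gave p = 0.1, the lowest that 3 against 3 can give. The uncalled list for ubiquitination and nuclear import of PTEN gave the same p in that test, so separation of scores is not particular to called lists. Camera called the sterol list higher at an adjusted p of 7.91e-16. With an estimated correlation the p was 0.0436 and the adjusted p 0.697. By edgeR, 17 members passed when adjusted over the list alone and 0 when adjusted over all genes tested. Idi1, the isopentenyl diphosphate isomerase of the mevalonate pathway, stood at 85.5 ± 3.84 CPM with isoleucine and 66.9 ± 5.18 with PBS (SD, n = 3), a log2 fold change of 0.35 ± 0.07 (SE). Hmgcr, the rate-limiting enzyme of cholesterol synthesis, stood at 111.0 ± 0.786 and 92.7 ± 5.86 CPM. Cyp51, the lanosterol demethylase, stood at 133.6 ± 7.35 and 103.2 ± 12.6 CPM. Skeletal muscle transcripts were lower in the same tumours, and with the muscle score as a covariate, an alternative chosen after the data were seen, the sterol median was 0.0833 and the camera call was lost at an adjusted p of 0.0825.

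Endothelial genes were lower with isoleucine. Of 24 measured members, 23 had a log2 fold change below 0, the median was -0.29 (0.818-fold), and all 3 isoleucine libraries scored below all 3 PBS libraries. The exact permutation p of these scores was also the lowest possible, 0.1. Camera called the list lower at an adjusted p of 1.53e-10. With an estimated correlation the p was 0.0152 and the adjusted p 0.606. By edgeR, 7 members passed when adjusted over the list alone and 0 over all genes. Pecam1, an adhesion molecule of endothelial junctions, stood at 56.8 ± 0.662 CPM with isoleucine and 71.7 ± 4.07 with PBS (SD, n = 3), a log2 fold change of -0.33 ± 0.06 (SE). Esam, another endothelial adhesion molecule, stood at 19.9 ± 1.06 and 26.0 ± 1.57 CPM, and Sox18, a transcription factor of blood and lymphatic vessels, at 14.2 ± 0.881 and 18.8 ± 1.57 CPM. The 18 pericyte and smooth muscle genes had a median of -0.13 and were not called, but were called lower without PBS library 2 (median -0.166) or PBS library 3 (-0.15), and had a median of -0.0688 without PBS library 1.

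Skeletal muscle and erythroid transcripts had the largest fold differences among the called lists, and both were lower with isoleucine. Of 36 muscle genes, 35 were below 0, with a median log2 fold change of -1.91 (0.266-fold). Camera called the list lower at an adjusted p of 1.11e-25. With an estimated correlation the p was 0.0725 and the adjusted p 0.697. By edgeR, 6 members passed when adjusted over the list alone and 0 over all genes. The muscle scores overlapped between groups, since PBS library 3 scored -0.14, isoleucine library 3 scored -0.05, and PBS libraries 1 and 2 scored 1.33 and 1.52. An exact two-sided permutation test of the scores gave p = 0.2, where 3 against 3 cannot go below 0.1. Myh2, a fast myosin heavy chain, stood at 1.62 ± 0.835 CPM with isoleucine and 10.2 ± 4.24 with PBS (SD, n = 3), a log2 fold change of -2.63 ± 0.48 (SE). The filament-associated genes Xirp1 and Xirp2 stood at 0.145 ± 0.070 and 0.902 ± 0.381 CPM with isoleucine, and at 1.28 ± 0.702 and 2.27 ± 0.491 CPM with PBS. Csrp3, a muscle LIM protein gene outside the list, stood at 0.411 ± 0.017 and 2.33 ± 1.33 CPM. The muscle list as a whole took at most 0.0851% of the counts of a library.

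All 8 measured erythroid genes were lower with isoleucine, with a median log2 fold change of -2.55 (0.171-fold). By edgeR, all 8 passed when adjusted over the list alone and 0 over all genes. Camera's estimated correlation between them was 0.961, so they are not 8 separate observations. Camera called the list lower at an adjusted p of 2.62e-11. With an estimated correlation the p was 0.0587 and the adjusted p 0.697. Alas2, the first enzyme of haem synthesis in red cell precursors, stood at 10.2 ± 4.61 CPM with isoleucine and 65.7 ± 36.0 with PBS (SD, n = 3). Bpgm stood at 21.2 ± 2.72 and 37.3 ± 10.6 CPM, and Snca at 1.79 ± 0.900 and 9.34 ± 5.06 CPM. The list took 1.06%, 0.635% and 0.277% of counts in PBS libraries 1 to 3, and 0.153%, 0.0636% and 0.137% in isoleucine libraries 1 to 3. The alpha-globin and beta-globin genes in this list are near-identical copies, so the division of counts among them is uncertain. With the muscle score as a covariate the erythroid median was -0.844, and camera still called the list lower at an adjusted p of 0.0101.

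Of 8 measured B cell and plasma cell genes, 7 were below 0, with a median log2 fold change of -1.26 (0.417-fold), and camera called the list lower at an adjusted p of 2.11e-05. With an estimated correlation the adjusted p was 0.697. By edgeR, 3 members passed when adjusted over the list alone and 0 over all genes. The 3 were Pou2af1 (a B cell coactivator), Cd79b (a B cell receptor subunit) and Cd22 (a B cell lectin). Pou2af1 stood at 0.263 ± 0.106 CPM with isoleucine and 1.14 ± 0.640 with PBS, Cd79b at 0.691 ± 0.229 and 2.14 ± 1.19, and Cd22 at 5.94 ± 1.12 and 8.82 ± 1.604 (SD, n = 3). The size depended on single libraries: the median was -0.476 without PBS library 2, -2.18 without PBS library 3, and -1.96 without isoleucine library 3. The muscle score moved with this list too, and with it as a covariate the median was -0.306 and the call was lost.

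Mitochondrially encoded genes were higher with isoleucine in 13 of 13 cases, with a median log2 fold change of 0.26 (1.2-fold). Camera called the list higher at an adjusted p of 2.68e-08. With an estimated correlation the p was 0.104 and the adjusted p 0.697. By edgeR, 7 members passed when adjusted over the list alone and 0 over all genes. The mt-Nd4l gene of respiratory complex I stood at 96.6 ± 2.14 CPM with isoleucine and 67.9 ± 10.4 with PBS (SD, n = 3), a log2 fold change of 0.52 ± 0.10 (SE). Its annotated position overlaps mt-Nd4, so its count is uncertain. Complex I gene mt-Nd5 stood at 421.2 ± 23.6 and 346.8 ± 10.0 CPM, and complex III gene mt-Cytb at 1696 ± 137.5 and 1372 ± 15.01 CPM. The list took 1.44%, 1.49% and 1.51% of counts in the PBS libraries and 1.61%, 1.53% and 1.93% in the isoleucine libraries. Its median was 0.171 without isoleucine library 3 and 0.434 with the muscle score as a covariate, called in both cases.

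Nuclear genes of oxidative phosphorylation and genes of cytosolic ribosomal proteins had smaller differences in the same direction. Of 74 nuclear genes of oxidative phosphorylation, 58 were above 0 (median log2 fold change 0.05), and camera called them higher at an adjusted p of 0.000569. Of 79 ribosomal protein genes, 63 were above 0 (median 0.05), and camera called them higher at an adjusted p of 0.00473. Both had an adjusted p of 0.999 with an estimated correlation. By edgeR, 0 members of either list passed when adjusted over the list alone. Cox7b, Ndufa6 and Ndufa1, subunits of respiratory complexes, stood at 138.1 ± 11.9, 71.4 ± 9.93 and 34.6 ± 2.04 CPM with isoleucine and at 114.5 ± 11.5, 58.6 ± 3.52 and 30.1 ± 0.738 with PBS. Isoleucine library 3 scored highest on both lists. Without it the medians were 0.00309 and -0.0297, and without PBS library 2 they were 0.0305 and 0.0155, and both calls were lost in each case. Without isoleucine library 2 they were 0.0923 and 0.0888, and with the muscle score as a covariate they were 0.102 and 0.16, with both lists called. Without isoleucine library 1 the ribosomal median was 0.086. The 38 ribosome biogenesis and MYC-linked genes had a median of 0.03 and were not called, but were called higher without PBS library 1 (0.0593), PBS library 2 (0.0401) or isoleucine library 3 (0.0561), and with voom values (0.0342); the median was -0.00642 without PBS library 3 and 0.0157 without isoleucine library 2.

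Hypoxia and glycolysis genes and fibroblast and extracellular matrix genes were called lower by camera, at adjusted p of 0.000652 and 0.00636. Both had an adjusted p of 0.999 with an estimated correlation, and 0 members of either list passed when adjusted over the list alone. Of 39 hypoxia and glycolysis genes, 36 were below 0 (median log2 fold change -0.07). The oxygen-sensing prolyl hydroxylase genes Egln3 and Egln1 stood at 209.9 ± 16.2 and 86.7 ± 3.29 CPM with isoleucine and 244.9 ± 19.2 and 94.3 ± 0.177 with PBS, and the glycolytic gene Aldoa at 945.8 ± 81.5 and 1077 ± 74.6. The hypoxia call was lost without PBS library 1 or isoleucine library 2 (medians -0.0538 and -0.0315), and the median was -0.118 without PBS library 3. Of 35 fibroblast and matrix genes, 29 were below 0 (median -0.27). PBS library 3 scored -0.496 on that list and PBS libraries 1 and 2 scored 0.613 and 0.345. The matrix median was -0.499 without PBS library 3, and the call was lost without PBS library 1 or isoleucine library 1 (medians -0.115 and -0.274). With the muscle score as a covariate both medians turned positive, to 0.0783 and 0.442, with neither called.

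**Figure D2:**
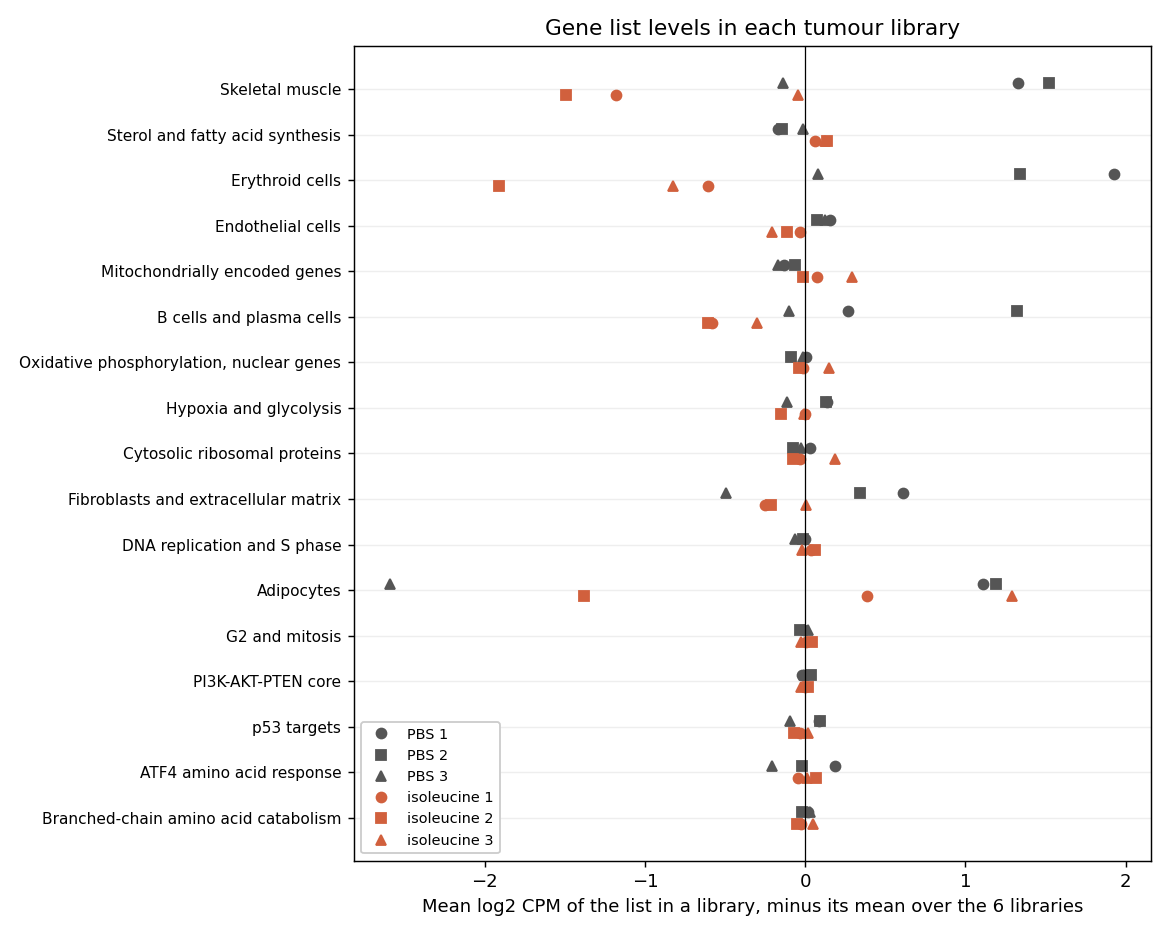
Mean log2 CPM of each gene list in each library, minus its mean over the 6 libraries (horizontal axis, log2 units), for the 11 lists called by camera and 6 others, with PBS libraries in grey, isoleucine libraries in orange, and replicates 1, 2 and 3 as circles, squares and triangles. Sterol and endothelial scores do not overlap between groups, with differences between group means of 0.217 and -0.237, while muscle scores overlap at PBS library 3 and isoleucine library 3, and adipocyte scores spread from -2.59 to 1.29 without following the groups.

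Among genes averaging at least 1 CPM whose groups did not overlap, leaving out unnamed gene models, the smallest p-values on the higher side belonged to Per1, Cav2, Idi1, Psd3 and mt-Nd4l, and none passed edgeR's adjusted threshold. Per1, a core repressor of the circadian clock, stood at 100.8 ± 11.6 CPM with isoleucine and 57.7 ± 6.05 with PBS (SD, n = 3), a log2 fold change of 0.81 ± 0.10 (SE) with an edgeR adjusted p of 0.158. Cav2, which encodes caveolin-2, stood at 62.8 ± 1.91 and 48.1 ± 1.05 CPM, with an edgeR adjusted p of 0.158, and Psd3 at 41.1 ± 0.599 and 32.5 ± 1.24 CPM. On the lower side they belonged to Apoe, Pecam1, Csrp3, Selenop and Pnrc1. Apoe, the gene of the lipid carrier apolipoprotein E and a member of the macrophage list, stood at 1046 ± 19.3 CPM with isoleucine and 1444 ± 131.2 with PBS, a log2 fold change of -0.46 ± 0.07 (SE) with an edgeR adjusted p of 0.177. Selenop, the plasma selenium carrier, stood at 248.3 ± 26.6 and 327.2 ± 12.8 CPM, and Pnrc1 at 44.9 ± 2.02 and 55.4 ± 1.22. DESeq2 gave adjusted p-values of 1.89e-10 for Per1, 4.52e-08 for Apoe, 0.000408 for Selenop and 0.0034 for Cav2. Without PBS library 3, edgeR's adjusted p was 0.012 for Per1, 0.0304 for Apoe, 0.0354 for Cav2 and 0.0371 for Pecam1.

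Lists tied to amino acid metabolism, and the immune lists other than B cells and plasma cells, were not called with all 6 libraries. The 38 genes of the ATF4 amino acid response had a median log2 fold change of 0.001, with 19 above 0 and 19 below. Without PBS library 1 its median was 0.108 and it was called higher at an adjusted p of 0.000137, and without PBS library 3 its median was -0.0497 and it was not called. The 31 genes of branched-chain amino acid catabolism had a median of -0.02, and the 34 genes of amino acid transport and sensing also had a median of -0.02. T cell genes varied more between libraries of a group than between groups. Their scores were -0.254, 0.533 and -0.354 in PBS libraries 1 to 3 and 0.344, -0.542 and 0.272 in isoleucine libraries 1 to 3, and the list median was 0.07. Medians were -0.04 for 43 interferon response genes, 0.02 for 19 MHC class I genes, -0.18 for 11 MHC class II genes, -0.08 for 18 cytotoxic lymphocyte genes (-0.283 without PBS library 3 and 0.238 without PBS library 2, called in neither) and -0.04 for 17 checkpoint and regulatory T cell genes. The interferon median ran from -0.288 to 0.189 and the MHC class I median from -0.166 to 0.195 when 1 library was left out, and each of these lists was called in 3 of the 6 such fits. Interferon genes were called higher without PBS library 2 and lower without PBS library 3 (-0.173) or isoleucine library 1, and MHC class I genes higher without PBS library 2 or isoleucine library 2 (0.152) and lower without isoleucine library 1. MHC class II genes were called lower without PBS library 1 (-0.377), PBS library 3 (-0.299) or isoleucine library 1 (-0.492), with a median of 0.152 without PBS library 2, and T cell genes were called higher without PBS library 2 (0.377) or isoleucine library 2 (0.343). The T cell median was -0.0601 without PBS library 1, -0.107 without PBS library 3, -0.13 without isoleucine library 1 and -0.0839 without isoleucine library 3. Checkpoint genes were called higher without PBS library 2 (0.373) and had a median of -0.238 without isoleucine library 1. Macrophage genes had a median of -0.03 (-0.088 and called lower without PBS library 3, 0.0079 without PBS library 2), and of 25 members Apoe alone passed edgeR when adjusted over the list alone. The 23 neutrophil genes had a median of -0.64, with PBS scores of 0.341, 1.34 and -1.09, and were not called. They were called lower without PBS library 3 (-1.05) and with the adipocyte score as a covariate (-0.558), while the median was 0.0358 without PBS library 2 and -0.0309 with voom values, called in neither. Medians were -0.04 for dendritic cells, -0.25 for mast cells, -0.13 for adipocytes, 0.007 for keratinocytes, -0.02 for nerve and Schwann cells, 0.02 for apoptosis genes, 0.02 for epithelial and mesenchymal state, -0.04 for immediate early genes and 0.008 for heat shock genes. Adipocyte genes were called lower without PBS library 3 (-0.581), with medians of -0.984 without isoleucine library 3 and 0.118 without PBS library 2, and immediate early genes were called higher without PBS library 2 (0.0825) and lower without PBS library 3 (-0.116). With the muscle score as a covariate, in a fit with 3 residual degrees of freedom, camera called 6 more lists higher: adipocytes (median 3.67, adjusted p 7.22e-19), neutrophils (1.18), T cells (0.718), checkpoints (0.709), keratinocytes (0.38) and immediate early genes (0.364). Among the lists called in no fit that left out 1 library, all but the G1 cyclins and kinase inhibitors had a median that turned sign in at least 1 such fit. For dendritic cells, adipocytes, nerve cells, immediate early genes, keratinocytes, MHC class I, heat shock genes and epithelial and mesenchymal state, the median and camera's direction differed in sign.

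Camera with its preset correlation called 5 of the 40 lists higher and 6 lower, and with a correlation estimated for each list it called 0, with a smallest adjusted p of 0.606 and 2 lists under an unadjusted p of 0.05. Fry, a rotation test of each list by itself, called 0 lists in a single direction (smallest adjusted p 0.272, with 4 lists under an unadjusted p of 0.05), and its test for change in either direction called 1, the endothelial list, at an adjusted p of 0.0334.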

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

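The covariate fits were chosen after the data were seen; the other alternatives were set beforehand. Both counts of single genes were 0 in the main edgeR test (684 genes at an unadjusted p under 0.05) and stayed at 0 under the other scalings, the stricter filter, limma-voom, the non-robust fit and the muscle score covariate. Both other thresholds also gave 0, as they had to with a smallest adjusted p of 0.158 in the same edgeR fit. Genes were called with no low-count filter (1 higher, 1 lower), with DESeq2 (17 higher, 32 lower), with voom sample weights (1 higher) and with the adipocyte score as a covariate (9 higher, 50 lower). Leaving out 1 library gave 0 to 13 genes higher and 0 to 90 lower; the 13 and the 90 came without PBS library 3, and 1 higher came without PBS library 2. DESeq2 and the fit without PBS library 3 called 49 and 103 genes, with 24 in both. The cause was not tested. Pten ranged from -0.0156 to 0.0809 in log2 fold change over 17 alternatives, with a smallest adjusted p of 0.843, and turned negative only with the muscle covariate. The other 38 named genes gave 643 values under alternatives, of which 40 were called and 6 changed sign.

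Of the list counts, 5 higher and 6 lower, an estimated correlation gave 0 and 0 and fry gave 0 and 0. The muscle covariate gave 9 higher and 2 lower, and leaving out 1 library gave 4 to 9 higher (9 without PBS library 2) and 5 to 13 lower (13 without PBS library 3). Endothelial, sterol, muscle, erythroid, mitochondrially encoded and B cell lists were called in the same direction in all 6 fits that left out 1 library. Those fits used the preset correlation and share most of their libraries, so they do not test these calls against correlation between genes. Of the 29 uncalled lists, 14 were called in some alternative. Among lists called with or without the change of setting, the muscle covariate turned camera's direction to higher for hypoxia and glycolysis (median 0.0783), checkpoints (0.709), neutrophils (1.18), fibroblasts (0.442) and keratinocytes (0.38). Leaving out 1 library turned it for ribosomal proteins (-0.0297 to 0.0888; lowest without isoleucine library 3), interferon response (-0.288 to 0.189), MHC class I (-0.166 to 0.195), checkpoints (-0.238 to 0.373), adipocytes (-0.984 to 0.118) and immediate early genes (-0.116 to 0.0825). The cause of these turns was not tested. The median of all genes moved by at most 0.00252 between scalings. Library totals of 13216697 to 27258142 counts limit the least abundant genes, such as Xirp1, more than Pten or Apoe.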

Other observations

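The tests of the muscle, erythroid and sterol lists and of Per1, including every fit with a muscle or adipocyte score, were chosen after the results they bear on were seen; the regrouping of libraries was set before. Genes in the next 2 paragraphs were chosen after their values were seen.

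Some extracellular matrix genes separated PBS library 3 from the other PBS libraries. The score of the fibroblast and matrix list did so too (0.613, 0.345 and -0.496 in PBS libraries 1 to 3). Its summed CPM did not, at 9735, 7775 and 8383. Eln, the gene of elastin, stood at 43.5, 39.2 and 5.82 CPM in PBS libraries 1 to 3 and at 7.76, 7.14 and 9.17 CPM in isoleucine libraries 1 to 3. Lox, which encodes the enzyme that cross-links collagen and elastin, stood at 18.3, 17.7 and 1.42 CPM with PBS and 4.24, 3.91 and 4.73 with isoleucine, and the proteoglycan gene Bgn at 102.5, 86.7 and 24.7 CPM with PBS and 35.7, 38.9 and 41.6 with isoleucine. Without PBS library 3, the 90 genes called lower by edgeR included 10 of the fibroblast and matrix list, 8 of the muscle list and 4 each of the erythroid and B cell lists, and the 13 called higher included 7 of the sterol list. The leading component of variation (44.9% of the variance) had adipocyte genes such as Cidec, Adipoq and Plin1 at the end of PBS libraries 1 and 2, and placed PBS library 3 at 25.4 beside isoleucine library 2 at 24.3. The second component (18.2%) placed the PBS libraries at 12.5, 2.28 and 20.6 and the isoleucine libraries at -15.5, -9.38 and -10.6, with muscle and erythroid genes such as Myh2, Xirp1, Alas2 and Hbb-bt at the PBS end and fat genes such as Ucp1, Cidec and Plin1 at the isoleucine end.

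Other fits called genes that edgeR with all 6 libraries did not. Spp1, the gene of the secreted protein osteopontin, stood at 966.3 ± 29.4 CPM with isoleucine and 811.4 ± 28.5 with PBS (SD, n = 3), with an adjusted p of 0.00269 by DESeq2 and 0.642 by edgeR. Stra6, a retinol transporter, stood at 309.0 ± 18.2 and 255.4 ± 9.30 CPM, with a DESeq2 adjusted p of 0.017. Trf, the gene of transferrin, stood at 81.2 ± 9.47 and 128.7 ± 27.3 CPM, with a DESeq2 adjusted p of 0.000351. The small heat shock genes Cryab and Hspb1 stood at 2.54 ± 0.661 and 3.64 ± 0.421 CPM with isoleucine and 7.32 ± 2.50 and 7.23 ± 2.03 with PBS. They were the 2 heat shock genes that passed edgeR when adjusted over the list alone. DESeq2 called Cryab (adjusted p 0.00215) and not Hspb1. The heat shock list as a whole was not called, with 10 members above 0 and 9 below. Among PBS libraries both genes were lowest in library 3 (4.44 and 4.98 CPM), where the muscle score was also lowest. Whether they go with muscle was not tested. The calls of DESeq2 and of the fits without a filter or with sample weights also included gene models that overlap other genes on the same strand. Gm43064, which overlaps Ap4b1 and Bcl2l15, was counted at 0 CPM in all 3 PBS libraries and at 1.58, 1.3 and 0.764 CPM with isoleucine. Pagr1a, which overlaps Pagr1b, stood at 0.418, 0 and 0.654 CPM with PBS and 3.07, 3.63 and 6.92 with isoleucine, and Gm45140, which overlaps Isy1 and Rab43, at 15.3, 14.7 and 13.2 and 8.03, 6.34 and 8.02. How counts were divided within such overlaps is uncertain.

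The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping called 0 genes at an adjusted p under 0.05 and the highest of the others also 0, so all 10 gave as many. At an unadjusted p under 0.05 the real grouping gave 684 genes and the highest other 890, with 5 of the 10 giving as many. Camera called 11 lists in the real grouping and 20 in the highest other, with 7 of the 10 giving as many. The 20 came from PBS libraries 1 and 2 with isoleucine library 1 against the rest. All groupings used camera's preset correlation of 0.01, which is low for lists whose members vary together. The counts therefore cannot show whether the samples hold a structure beside the treatment.

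Skeletal muscle and erythroid transcripts were lower together with isoleucine, and a candidate explanation is that pieces of tumour margin with different amounts of muscle and blood were sampled. The 32 muscle genes averaging at least 1 CPM also varied together within the groups. With each group mean taken out, their median pairwise correlation was 0.908, against 0.255 at most in 1000 random lists matched on expression. Different amounts of muscle tissue, or shared regulation, would give this. Random lists are a weak comparison, since some other lists also varied together. Camera's estimated correlation was 0.958 for MHC class I and 0.784 for ribosomal proteins, against 0.746 for muscle. Whether the muscle genes kept 1 ratio was not tested. Myh2 was 0.161-fold and Xirp2 0.403-fold with isoleucine. Their log2 fold change intervals overlap, at -3.796 to -1.473 for Myh2 and -2.097 to -0.5246 for Xirp2. Eno3, the 1 member of the muscle list above 0, stood at 90.2 CPM with isoleucine and 89.3 with PBS. Its interval, -0.1032 to 0.1334, overlapped neither. It stood at 92.7, 90.3 and 85.0 CPM in PBS libraries 1 to 3, where the muscle score was 1.33, 1.52 and -0.138. Overlap of such intervals does not test for 1 ratio, since the genes share libraries. Acta1 stood at 23.2 ± 12.4 CPM with isoleucine and 118.8 ± 73.4 with PBS. The haemoglobin gene Hbb-bs stood at 451.7 ± 183.1 and 2408 ± 1394. Of the 36 muscle genes, 1 is also in another list. With the muscle score as a covariate the erythroid median went from -2.55 to -0.844, the direction that blood coming with muscle would give, but camera still called the list lower (adjusted p 0.0101) and the treatment difference of its scores was -0.845 ± 0.831 (SE over libraries), in a fit with 3 residual degrees of freedom and a score that itself differs with treatment. How much of the erythroid difference goes with muscle stays open, as does an effect of isoleucine on invasion into muscle or on bleeding, which was not tested.

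Sterol and fatty acid synthesis genes were higher with isoleucine, and a candidate biological explanation is a response of sterol synthesis to the treatment. Different amounts of fat tissue would need adipocyte scores that follow the groups. They did not, at 0.0962 ± 1.36 with isoleucine and -0.0962 ± 2.16 with PBS (SD, n = 3). A covariate so little related to treatment could hardly move the sterol median (0.233 with it and 0.219 without), so that fit adds no support. Dilution by muscle RNA would need 14.1% of dilution to give the median, and the muscle list took at most 0.0851% of the counts of a PBS library. Those counts come from 36 list genes, and their share of all muscle RNA was not measured. The gap therefore argues against dilution only as far as the list stands for muscle RNA. A larger share of tumour cells that raised all their transcripts alike would give the sterol and proliferation lists the same median. The sterol median was higher by 0.191 (bootstrap SE over genes 0.0202). That SE treats genes as independent and leaves out the spread between libraries, so it does not settle this explanation. A difference in margin tissue that the muscle score tracks stays open too: with that covariate the sterol median fell to 0.0833 (bootstrap SE over genes 0.0255). In the same fit, where the score and the treatment are partly confounded, the endothelial median stayed at -0.281.

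Per1 was 1.75-fold higher with isoleucine, the smallest edgeR p among genes higher with isoleucine, though not past the adjusted threshold. Candidate explanations are a different clock phase at tissue collection, more glucocorticoid signalling in the treated mice, or a response of the tumour to isoleucine, which was not tested. Of 9 other clock-controlled genes, 8 were above 0 (median log2 fold change 0.149, bootstrap SE over genes 0.0334). Camera gave p = 0.0256 with the preset correlation and p = 0.273 with an estimated correlation. Limma's rotation test fry gave p = 0.262 and an exact permutation test of the list scores gave p = 0.4. Of 16 other glucocorticoid-induced genes, 5 were above 0 and 11 below, with p = 0.917 by fry and p = 0.8 by the exact permutation test. Klf9 (log2 fold change 0.406) and Sgk1 (0.198) were among the 5, at unadjusted edgeR p of 0.0146 and 0.0402. Tsc22d3, left out of that list, stood at 70.8 ± 7.57 CPM with isoleucine and 51.9 ± 4.46 with PBS. Its adjusted p was 0.00581 by DESeq2 and 0.4545 by edgeR. Collection times are not in the labels and 3 libraries against 3 cannot go below 0.1 in the exact test, so the explanations cannot be told apart.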
